A study of Homo sapiens with 24 samples.

How the data were processed

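RNA was measured in A375, an established human malignant melanoma line, in 24 libraries that fall into 8 groups of 3. Cells received DMSO (the solvent), nucleotides, A771726 at 25 µM, or A771726 with nucleotides, for 24 or 48 h. Per the labels, total RNA was depleted of ribosomal RNA before library preparation and paired-end sequencing. Per the submitters' processing notes, reads were trimmed with cutadapt (version not given in the sources used here), aligned to hg19 with TopHat2 2.0.11 and quantified with Cufflinks 2.2.1. Filters, strand setting, gene annotation and the nucleotides' identity and dose are not given in the sources used here. A treatment note in the labels describes fixation for chromatin immunoprecipitation, which belongs to another assay and was not used.

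The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library) per gene, with 1 column per library and no counts. The authors' FPKM values were used as deposited for 25268 genes. Column sums differ between libraries, so the values are not TPM. Read depth is therefore unknown, and no count test could be run. Among all 276 pairs of libraries, at most 0.0117% of the genes above 0 in both had identical values, and the highest Pearson correlation was 0.969 across genes. No pair was treated as a repeat of the same library.

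A log2 value was computed here from the deposited FPKM after adding 1, and genes with a mean of at least 1 FPKM over all 24 libraries were kept (12042 genes). Group means were fitted with limma 3.58.1 in R 4.3.3, with all 24 libraries in 8 groups, without trend, robust estimation or replicate block. The 8 groups shared an estimate of the spread because each holds only 3 libraries. P-values were Benjamini-Hochberg adjusted within each of 12 comparisons, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. On data simulated for A771726 against DMSO at 24 h over 12042 genes, 12% of the genes changed by log2 1 and 65% of those changed by log2 2 were called, with 6 false calls. With the other 23 libraries, leaving out replicate 2 of A771726 at 48 h, the same simulation gave 46%, 92% and 11. The simulation gave every group the same spread for a gene and changed only genes with a mean log2 value above 3. These rates therefore do not cover groups of unequal spread or low genes.

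The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Named genes are the 10 with the largest positive and the 10 with the largest negative log2 fold change in each of the 4 main comparisons (A771726 against DMSO, and A771726 with nucleotides against A771726, at both times). They had to pass the test, reach a mean of 5 FPKM in the higher group and have all 3 libraries of the higher group above all 3 of the lower. Other comparisons took 5 and 5. Symbols with the usual prefixes of short RNAs and clone names were left out. DHODH, DDX21, HEXIM1, CDK9 and CDKN1A were named whatever their values. From each gene list, up to 4 members that passed (by fold change) and up to 2 that did not (by mean FPKM) could be named.

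The 24 fixed lists covered pyrimidine and purine synthesis and salvage, p53 targets, DNA replication and S phase, G2/M and mitosis, and replication-dependent histones. They also covered P-TEFb with its partners, the nucleolus, cytosolic ribosomal proteins, snoRNA host genes, the integrated stress response, the interferon response and NF-kB with inflammatory cytokines. The rest were cholesterol synthesis, immediate early genes, aryl hydrocarbon receptor targets, pigment cell differentiation, the neural crest state, hypoxia, the mitochondrial genome, apoptosis regulators, and markers of keratinocytes, fibroblasts with endothelium, and leukocytes. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether the members move 1 way on balance. Camera values were adjusted over the lists within a comparison. No gene of the mitochondrial genome list was found under its symbol in the table.

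The alternatives planned were a pseudocount of 0.1, no filter or a mean of at least 5 FPKM, median-of-ratios, quantile and TPM scaling, limma-trend with robust estimation, only the groups compared, a replicate block and leaving out each library. After the values were seen, fits were added with the other 23, 22 or 20 libraries, with zeros of expressed genes set to missing, and with the trend of each library on GC content and transcript length removed. Length and GC content were those of the longest annotated transcript of each gene. They came from another build and annotation than the submitters used, and matched 11259 of the tested genes by symbol (93.5%). No coordinates were taken from it. Same-numbered DMSO libraries at 24 and 48 h deviated together from their groups (correlations from 0.13 to 0.30 across genes in 3 of 3 pairs), so the comparison of DMSO over time was also fitted with the number as a block.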

Results

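A375 cells were profiled under A771726, the active metabolite of leflunomide. It inhibits DHODH, the mitochondrial enzyme of de novo pyrimidine synthesis. DMSO, nucleotides alone, A771726 and A771726 with nucleotides were each measured after 24 and 48 h, with 3 libraries per group. The deposited FPKM carry no counts, so depth is unknown. Sums of FPKM ran from 459300 to 773000 in 22 libraries. Replicates 1 and 2 of A771726 at 48 h stood apart, with sums of 231100 and 2284000. In replicate 2, the microRNA gene MIR3687 held 60.8% of the sum, and 16198 genes were listed at 0, against 6757 to 8101 in the other 23 libraries. Its median Spearman correlation with the other libraries was 0.178, that of replicate 1 was 0.747, and those of the other 22 were 0.905 to 0.970. Of 5460 tested genes with a group median of at least 10 FPKM, 53 were listed at 0 in all 3 libraries of some group. The translation factor EEF1A1, which every cell uses, is among them, so such genes are only reported as listed at 0. Nothing in the labels says that the libraries of a group are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

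**Figure D1:**
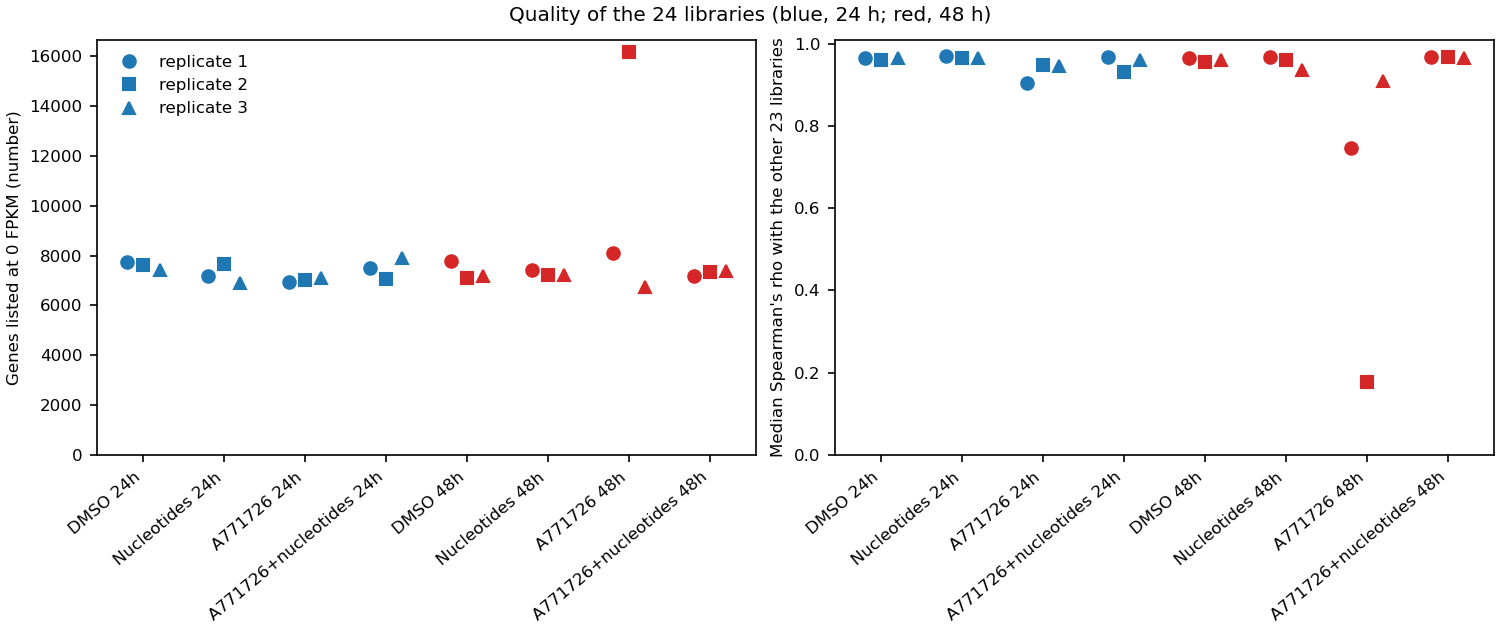
Genes at 0 FPKM (left, count) and median Spearman correlation with the other libraries (right), for each of the 24 libraries by group, with blue for 24 h, red for 48 h and symbols for replicates. Replicate 2 of A771726 at 48 h lies apart at 16198 genes and 0.178.

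The comparison of A771726 with DMSO at 24 h asked what the inhibitor does early. Targets of the tumour suppressor p53 were higher. GDF15, a stress cytokine, rose from 0.936 ± 0.122 to 23.5 ± 3.75 FPKM (SD, n = 3 libraries per group, log2 fold change 3.65 ± 0.58 SE, limma, adjusted p = 0.00243). BTG2, an antiproliferative gene, rose from 1.45 ± 0.0932 to 14.8 ± 1.96 FPKM (log2 fold change 2.69 ± 0.28, limma, adjusted p = 2.62e-05). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 29.5 ± 3.72 to 126.5 ± 12.9 FPKM (log2 fold change 2.07 ± 0.36, limma, adjusted p = 0.00447). Histone transcripts were lower, led by HIST1H2BB, which fell from 919 ± 56.6 to 119 ± 68.8 FPKM (log2 fold change -3.19 ± 0.52, limma, adjusted p = 0.00269).

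Of the 32 measured p53 targets, 10 rose and none fell, and 20 rose when adjusted over the list alone. Their median log2 fold change was 1.36, and camera gave an adjusted p = 1.23e-36 at the preset correlation and 9.27e-04 with an estimated correlation. TP53I3 rose by 2.71 and BBC3, a proapoptotic BCL2 family gene, by 2.34 on the log2 scale. MDM2, the p53 ubiquitin ligase, did not pass, with a log2 fold change of 1.38 ± 0.66 (limma, adjusted p = 0.601). Other genes among the 10 with the largest rises were PVRL4, the metabolic regulator TXNIP (from 3.80 ± 0.643 to 25.9 ± 4.45 FPKM), ARNT2, LINC01021 and FDXR, with log2 fold changes from 2.32 to 2.95. PLCG2 passed too but is listed at 0 in all 3 DMSO libraries and at 566.5, 1165 and 1075 FPKM under A771726, so no fold is given.

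All 29 replication-dependent histone genes were measured, 12 fell and none rose, and 26 fell when adjusted over the list alone. The median log2 fold change was -1.60, with a camera adjusted p = 8.31e-44 and adjusted p = 0.00778 with an estimated correlation. HIST1H1A fell from 76.3 ± 6.14 to 10.5 ± 3.38 FPKM, and HIST1H4C, which did not pass, averaged 2055 ± 141.9 and 874 ± 396.4 FPKM. Of the 10 largest falls, 9 were histone genes, among them HIST3H2A (log2 fold change -3.06), HIST3H2BB (-2.85), HIST1H3J (-2.72) and HIST1H2BG (-2.25). The remaining gene was LINC01029 (-2.55). These genes form families of near-identical copies, so the share of reads that went to each member is uncertain.

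Of 37 genes of DNA replication and S phase, 3 fell (MCM5, UHRF1 and MCM3), 8 adjusted over the list alone. Their median was -0.36 but 0.12 under TPM scaling, and camera gave adjusted p = 0.0208 with an estimated correlation. TPM scaling also raised the median of all genes, to above 0.12. MCM5, a subunit of the replicative helicase, fell from 51.4 ± 7.60 to 14.4 ± 3.74 FPKM. Of 18 snoRNA host genes, 4 fell (10 adjusted over the list alone), with a median of -1.18 (camera, adjusted p = 0.00778 with an estimated correlation). SNHG12 fell from 30.9 ± 1.52 to 6.01 ± 1.26 FPKM and SNHG5 from 161.9 ± 6.88 to 44.9 ± 6.30 FPKM. Of 50 nucleolar and ribosome biogenesis genes, NPM1, EBNA1BP2 and DKC1 fell (6 adjusted over the list alone), with a median of -0.52 (camera, adjusted p = 0.00778 with an estimated correlation). NPM1, the nucleolar protein nucleophosmin, fell from 1596 ± 217.6 to 652.3 ± 150.3 FPKM.

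Of 71 ribosomal protein genes, RPL23 fell, 13 fell adjusted over the list alone, and the median was -0.76 but 0.01 under quantile normalization (camera, adjusted p = 0.0796 with an estimated correlation). In the integrated stress response list of 29 genes, ATF4, its transcription factor, and ASNS, asparagine synthetase, fell by 1.22 and 1.18 on the log2 scale. Adjusted over the list alone, 2 rose and 5 fell (median -0.50, camera, adjusted p = 0.206 with an estimated correlation). Among 23 interferon response genes, IFIT1 and OAS2 rose (3 adjusted over the list alone), with a median of 0.57 (camera, adjusted p = 0.00778 with an estimated correlation). IFIT1 averaged 1.06 ± 0.128 FPKM in DMSO and 2.82 ± 0.539 FPKM under A771726. Of 13 NF-kB and cytokine genes, TNFAIP3 rose, the only call of the list alone too, with a median of 0.60 (camera, adjusted p = 0.0796 with an estimated correlation).

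No gene of pyrimidine (27 measured) or purine (18 measured) synthesis and salvage was called by limma, nor adjusted over the list alone, with medians of -0.23 and -0.26 that turned to 0.24 and 0.23 under TPM scaling. Their camera calls ended with an estimated correlation (adjusted p = 0.50 and 0.42). The 34 G2/M genes had no call over all genes and 2 falls adjusted over the list alone (median -0.20, 0.28 under TPM scaling, camera, adjusted p = 0.253 with an estimated correlation). TPM scaling raised the median of all genes too, to above the medians of these pyrimidine, purine and G2/M lists. NR4A1 rose among 18 immediate early genes, with 2 adjusted over the list alone (median 0.32, camera, adjusted p = 0.482 with an estimated correlation). The 23 hypoxia and glycolysis genes had no call either way (median 0.30, camera, adjusted p = 0.487 with an estimated correlation). CYP1A1 rose by 1.75 on the log2 scale among 5 aryl hydrocarbon receptor targets, also the only call adjusted over the list alone, with a median of 0.03 and a mean of 0.54.

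Camera at the preset correlation did not call P-TEFb with its partners (28 measured, median 0.07), cholesterol synthesis (22), pigment cell genes (11, median 0.53), the neural crest state (25, median -0.18), apoptosis regulators (17) or keratinocyte markers (6, median 0.18). Adjusted over the list alone, 1 cholesterol gene rose and the rest of these lists had no call. The cholesterol list had a median of -0.04 and a mean of 0.01, and the apoptosis list a median of -0.03 and a mean of 0.06. Only 2 of 15 leukocyte markers passed the filter: CD68 rose from 1.97 ± 0.254 to 9.33 ± 0.456 FPKM, and LYZ, at 5.88 ± 0.367 and 21.3 ± 6.65 FPKM, was called adjusted over the list alone. LUM and PDGFRB, the only measured markers of fibroblasts and endothelium, had log2 fold changes of 0.85 and 0.53 and were called adjusted over the list alone. These markers moved in the same libraries as the p53 targets.

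DDX21, the RNA helicase named in the series title, averaged 94.8 ± 11.7 FPKM in DMSO and 53.6 ± 6.57 FPKM under A771726 at 24 h (log2 fold change -0.81 ± 0.31, limma, adjusted p = 0.372). With the other 23 libraries the same change gave a limma adjusted p = 0.00207. DHODH averaged 8.53 ± 0.135 and 5.27 ± 0.679 FPKM (log2 fold change -0.61, limma, adjusted p = 0.993, and 0.0119 with the other 23 libraries). HEXIM1, an inhibitor of P-TEFb, and CDK9, its kinase, had log2 fold changes of 0.26 and 0.20 with a limma adjusted p = 1 each.

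Of 12042 genes, 59 were higher and 55 lower at 24 h, with 49 and 46 of them changed at least 2-fold on this scale. With the other 23 libraries, which leave out replicate 2 of A771726 at 48 h, 836 were higher and 569 lower, all 114 included. In that fit the estimated correlation ended the list calls of histones (adjusted p = 0.0916), S phase (0.170) and snoRNA hosts (0.0665), and kept p53 targets and interferon genes (0.0304 each) and the nucleolus (0.0378). TPM scaling moved the median of all genes from 0.03 to 0.46 and the calls to 145 higher and 9 lower, while a minimum mean of 5 FPKM and no filter gave 72.3% and 26.9% lower against 48.2%.

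**Figure D2:**
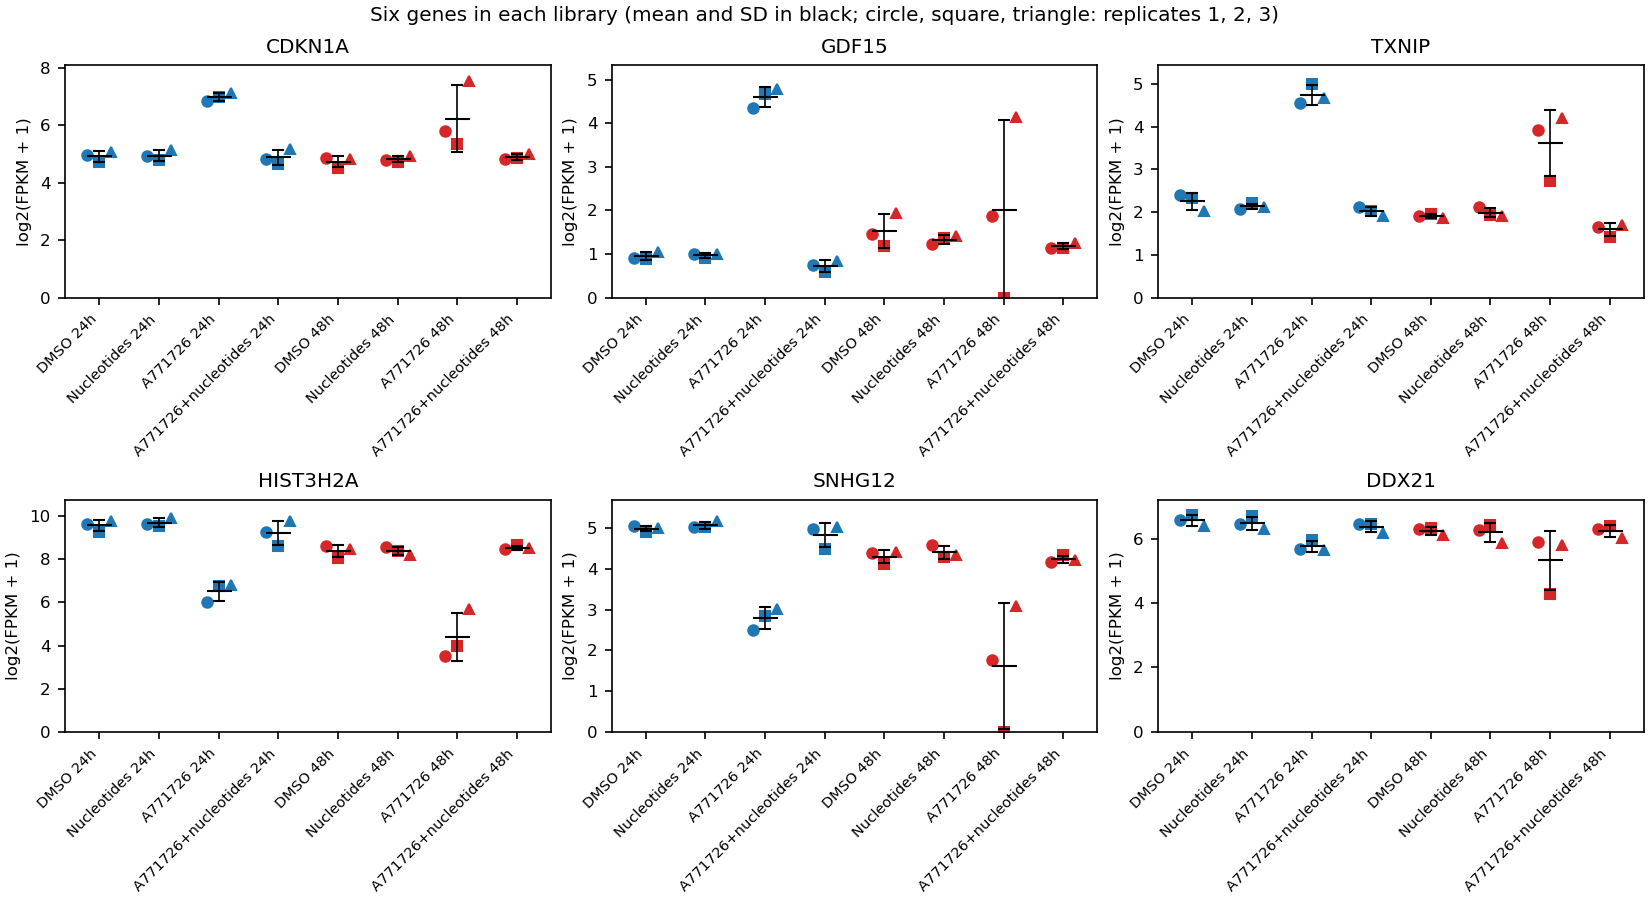
FPKM of CDKN1A, GDF15, TXNIP, HIST3H2A, SNHG12 and DDX21 on the log2(FPKM + 1) axis, with a point per library by group and the mean ± SD in black (n = 3). At 24 h GDF15 averaged 0.936 FPKM in DMSO, 23.5 FPKM under A771726 and 0.662 FPKM with nucleotides added.

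Adding nucleotides to A771726 asked whether the response depends on nucleotide supply. At 24 h, GDF15 fell from 23.5 ± 3.75 to 0.662 ± 0.150 FPKM (log2 fold change -3.88 ± 0.58, limma, adjusted p = 0.00183). TXNIP fell from 25.9 ± 4.45 to 3.06 ± 0.305 FPKM (-2.72 ± 0.26, limma, adjusted p = 2.22e-05). CDKN1A fell from 126.5 ± 12.9 to 29.1 ± 5.59 FPKM (-2.09 ± 0.36, limma, adjusted p = 0.00587). HIST3H2A rose from 92.9 ± 26.1 to 619.8 ± 235.1 FPKM (2.70 ± 0.40, limma, adjusted p = 0.00167), and SNHG12 rose from 6.01 ± 1.26 to 28.0 ± 5.51 FPKM (2.05 ± 0.45, limma, adjusted p = 0.0443).

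Of the p53 targets, 9 fell with nucleotides (21 adjusted over the list alone, median -1.44, camera, adjusted p = 1.48e-04 with an estimated correlation). Of the histone genes, 5 rose (23 adjusted over the list alone, median 1.35, camera, adjusted p = 0.00996 with an estimated correlation). Of the snoRNA hosts, 3 rose (6 adjusted over the list alone, median 1.08, camera, adjusted p = 0.00800 with an estimated correlation). EBNA1BP2 rose among the nucleolar genes (4 adjusted over the list alone, median 0.42, camera, adjusted p = 0.00996 with an estimated correlation). MCM5 and UHRF1 rose among the S phase genes (5 adjusted over the list alone, median 0.27, camera, adjusted p = 0.0306 with an estimated correlation). IFIT1 fell among the interferon genes (3 adjusted over the list alone, median -0.52, camera, adjusted p = 0.00321 with an estimated correlation). The keratin KRT8 fell by 2.43 and SHISA2 by 2.29 on the log2 scale, and the ribosomal protein paralog RPL22L1 rose by 1.79. CD68 fell by 1.95 on the log2 scale in the same libraries.

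In all, 29 genes were higher and 43 lower with nucleotides at 24 h, and 290 and 709 with the other 23 libraries, the 72 included. DDX21 had a log2 fold change of 0.61 ± 0.31 (limma, adjusted p = 0.919, and 0.0198 with the other 23 libraries), reaching 82.1 ± 9.64 FPKM. DHODH had a log2 fold change of 0.42, HEXIM1 of -0.12 and CDK9 of -0.05, each with a limma adjusted p = 1, and CDK9 stood at 0.01 under median-of-ratios scaling. This comparison shares its A771726 libraries with the comparison against DMSO, so chance values enter both with opposite signs. TPM scaling gave 91.7% and a minimum mean of 5 FPKM 45.5% lower genes against 59.7%.

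With nucleotides present, limma called few genes between A771726 and DMSO, in a fit whose spread includes replicate 2 of A771726 at 48 h. That spread limits what can be called, so few calls do not show that few genes differ. With the other 23 libraries limma called 2 genes at 24 h and 4 at 48 h (115 and 137 unadjusted), at a median standard error of 0.204 against 0.377. At 24 h limma called only PLCG2 (25 genes at an unadjusted p under 0.05), which is listed at 1175, 991.1 and 1141 FPKM against 0 in each DMSO library. At 48 h limma called 3 genes (47 unadjusted), of which EEF1A1 and ANKRD28 are listed at 0 in all 3 libraries with A771726 and nucleotides. The p53 targets had a median of -0.05 at 24 h and 0.01 at 48 h, and the histones of -0.32 and 0.06, with no member called by limma nor adjusted over the list alone. For the 24 h histones, camera gave adjusted p = 4.25e-10 at the preset correlation and adjusted p = 0.533 with an estimated correlation. At 24 h the slope of the A771726 response with nucleotides on the response without was 0.284 ± 0.041 across the 114 genes called at 24 h and 0.178 ± 0.155 across the 6915 genes called at 48 h. Each SD is over the libraries with A771726 and nucleotides (n = 3). The other groups were held at their means, so the SD leaves out their spread. With zeros of expressed genes set to missing, among them those of PLCG2, the 24 h slope over the genes called at 24 h in that fit was 0.0876. That set is not the same as the 114 genes. At 48 h the slope over the 6915 genes was 0.0046 ± 0.012, and over the 114 genes called at 24 h it was -0.022 ± 0.0095. The 48 h response without nucleotides rests on A771726 libraries of which replicates 1 and 2 stood apart. These 48 h slopes therefore do not show how much of a response nucleotides removed.

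For nucleotides alone against DMSO, limma called no gene at 48 h (37 at an unadjusted p under 0.05) and at 24 h only ANKRD28, listed at 0 in all 3 libraries with nucleotides and at 18.7 to 22.6 FPKM in DMSO (21 unadjusted). The medians of p53 targets were 0.02 at 24 h and 0.01 at 48 h. Those of histones were -0.01 and -0.13, the latter with camera adjusted p = 1.51e-04 at the preset correlation and adjusted p = 0.915 with an estimated correlation. With only the groups compared, limma called 4 genes at each time.

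**Figure D3:**
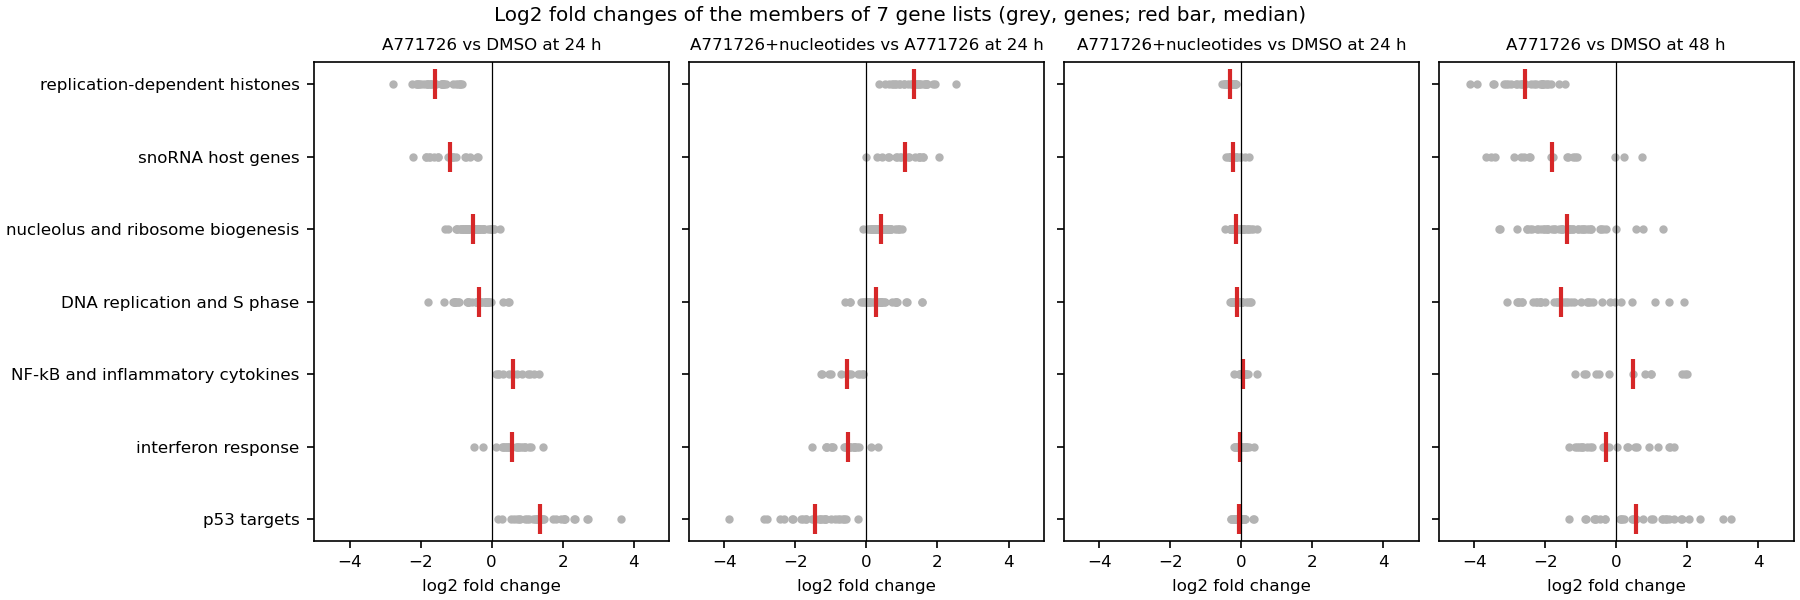
Log2 fold changes of the measured members of 7 gene lists in 4 comparisons, with grey points for genes and red bars for list medians. For A771726 against DMSO at 24 h the p53 targets centre on 1.36 and the histones on -1.60, against -0.05 and -0.32 with nucleotides, and the S phase median of -0.36 turns to 0.12 under TPM scaling. That scaling also lifts the median of all genes, to above 0.12. At 48 h the interferon median of -0.30 turns to 0.087, 0.59 and 0.064 under median-of-ratios, quantile and TPM scaling.

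The comparison of A771726 with DMSO at 48 h asked what the inhibitor does later. The mitotic activator CDC20 fell from 82.3 ± 8.02 to 8.43 ± 5.43 FPKM (SD, n = 3, log2 fold change -3.29 ± 0.27, limma, adjusted p = 4.80e-07). The helicase subunit MCM6 fell from 20.2 ± 4.87 to 2.24 ± 2.71 FPKM (-3.07 ± 0.41, limma, adjusted p = 4.97e-05). HIST2H2BA fell from 74.2 ± 12.7 to 4.21 ± 5.73 FPKM (-4.52 ± 0.52, limma, adjusted p = 1.76e-05). The neural crest receptor NGFR fell from 10.8 ± 1.42 to 0.326 ± 0.402 FPKM (-3.18 ± 0.24, limma, adjusted p = 1.48e-07). CDKN1A rose from 25.9 ± 3.37 to 94.3 ± 81.5 FPKM (limma, adjusted p = 0.00215), at 54.7, 40.1 and 188 FPKM in the A771726 libraries. These sets include both libraries that stood apart. Limma gives them a spread shared with groups that vary less, so these p-values may be too small.

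All 29 histone genes fell, over all genes and adjusted over the list alone (median -2.56, camera, adjusted p = 0.472 with an estimated correlation). Of the ribosomal protein genes 69 of 71 fell in both counts (median -1.69, adjusted p = 0.530 with an estimated correlation), RPL8 by 3.20 on the log2 scale. In both counts 26 of 37 S phase genes fell (median -1.55, adjusted p = 0.472 with an estimated correlation). Of 34 G2/M genes 28 fell, and 29 adjusted over the list alone (median -1.60, adjusted p = 0.311 with an estimated correlation), UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 3.93. Of the nucleolar genes 37 fell and 1 rose in both counts (median -1.39, adjusted p = 0.448 with an estimated correlation), with FBL, the fibrillarin gene, lower by 3.30. Of the p53 targets 14 rose and 2 fell in both counts (median 0.55, adjusted p = 0.191 with an estimated correlation). These medians stand against a median of all genes of -0.87.

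Among 13 NF-kB and cytokine genes, 4 rose and 2 fell (4 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.311 with an estimated correlation, and 0.0473 with the other 23 libraries). The median was -0.49 among members with a mean of at least 5 FPKM. BIRC3 rose by 1.98 and IL1A by 1.85, while TNFAIP2 fell by 1.15 on the log2 scale. The interferon genes had a median of -0.30 and 4 rises with 6 falls (2 and 6 adjusted over the list alone), which turned to 0.09 under median-of-ratios scaling, 0.59 under quantile normalization and 0.06 under TPM. The macrophage gene LYZ was at 36.3, 955.9 and 39.9 FPKM against 6.63 ± 1.01 FPKM in DMSO (3.90, and 2.37 without replicate 2), and CD68 rose by 1.72 on the log2 scale.

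DDX21 fell from 75.2 ± 6.29 to 44.4 ± 22.6 FPKM at 48 h (log2 fold change -0.91 ± 0.31, limma, adjusted p = 0.0180). Without replicate 2 its change was -0.38 (limma, adjusted p = 0.0658). HEXIM1 fell by 1.51 and CDK9 by 2.19 on the log2 scale, with limma adjusted p = 6.10e-04 and 0.00107, and their changes were -1.35 and -1.37 without replicate 2. These stand against a median of all genes of -0.87, and -0.64 without replicate 2. In replicates 1, 2 and 3 of A771726, HEXIM1 was at 1.33, 1.91 and 6.08 FPKM (9.42 ± 1.41 in DMSO) and CDK9 at 2.67, 0 and 7.44 FPKM (13.6 ± 3.16 in DMSO). DHODH had a log2 fold change of 0.23 (limma, adjusted p = 0.706), which reversed to -0.83 without replicate 2 (adjusted p = 5.86e-04).

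At 48 h limma called 511 genes higher and 6404 lower. With the other 23 libraries 735 were higher and 6576 lower, with 5642 calls shared, and without replicates 1 and 2 they numbered 826 and 2555. With only the groups compared, limma called 1 gene higher and 8 lower. The share of lower genes was 92.6%, against 65.9% with median-of-ratios scaling, 55.3% with quantile normalization and 73.7% with TPM, which moved the median of all genes from -0.87 to -0.37, -0.07 and -0.73.

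Fold changes of A771726 with nucleotides against A771726 at 48 h went the other way. This comparison reuses the A771726 libraries of the comparison with DMSO, so opposite signs follow in part from the sharing. Replicates 1 and 2 of these stood apart, so an effect of nucleotides and the state of the libraries cannot be told apart. UBE2S rose from 21.0 ± 26.5 under A771726 to 250.7 ± 15.1 FPKM with nucleotides (log2 fold change 4.26 ± 0.55, limma, adjusted p = 3.46e-05). HIST3H2A rose from 25.2 ± 21.7 to 372.8 ± 24.2 FPKM (4.14 ± 0.40, limma, adjusted p = 3.38e-06). All 29 histone genes and 69 of 71 ribosomal protein genes rose in both counts, and 14 of 32 p53 targets fell (medians 2.69, 1.68 and -0.70 against 0.86 for all genes, adjusted p = 0.473, 0.606 and 0.211 with an estimated correlation). EEF1A1 is listed at 0 with nucleotides and at 3349, 710.6 and 2196 FPKM under A771726. CDKN1A fell by 1.34, while DDX21, HEXIM1 and CDK9 rose by 0.90, 1.51 and 1.99 (limma, adjusted p = 0.00440, 0.0190, 5.76e-04 and 0.00203). Without replicate 2 of A771726, the change of DDX21 was 0.37 (limma, adjusted p = 0.0725) that of CDK9 1.16, and that of DHODH turned from -0.20 to 0.87.

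In total 6381 genes were higher and 522 lower with nucleotides at 48 h, or 6524 and 697 with the other 23 libraries. With only the groups compared limma called 8 genes. The share of lower genes was 7.56%, against 34.1% with median-of-ratios scaling, 41.9% with quantile normalization and 20.6% with TPM.

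The test of the difference between the A771726 effects with and without nucleotides called 1 gene higher and 8 lower at 24 h, among them BTG2, TXNIP and FDXR. It called 78 and 230 with the other 23 libraries, 165 and 399 with only the groups compared, and 11 and 23 with quantile normalization. At 48 h it called 3654 higher and 92 lower, but 330 and 170 with median-of-ratios scaling, 596 and 341 with quantile normalization, 175 and 65 with TPM, and 5 and 3 with only the groups compared. The difference between the A771726 effects at 48 h and 24 h was called for 31 genes higher and 3669 lower, with UBE2C and S100A11 among the lower and SCHIP1 among the higher. Those counts were 3 and 5 with median-of-ratios scaling, 253 and 323 with quantile normalization, 23 and 1830 with TPM, and 0 and 3 with only the groups compared (limma, 3126 unadjusted). SCHIP1 averaged 0.476 ± 0.145 FPKM in DMSO and 0.696 ± 0.365 FPKM under A771726 at 24 h, and 0.654 ± 0.615 and 8.09 ± 1.57 FPKM at 48 h.

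Between DMSO at 48 h and 24 h limma called no gene (145 at an unadjusted p under 0.05, and 3 with the other 23 libraries). Histones had a median log2 fold change of -0.73 (camera, adjusted p = 5.29e-34 at the preset correlation and adjusted p = 0.0503 with an estimated correlation). HIST1H4C averaged 2055 ± 141.9 FPKM at 24 h and 1272 ± 101.2 FPKM at 48 h in DMSO. S phase genes had a median of -0.36, with camera adjusted p = 0.0314 with an estimated correlation and no member called by limma, nor adjusted over the list alone.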

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

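The tests of a single library and of nucleotide shortage for the p53 targets, of genes as short as histones, of A771726 treatment for the 48 h fall, and of splits that part the A771726 libraries, were chosen after the result was seen, as were the values with the other 23 libraries. What brought the results of this part here is a tested difference between effects: of A771726 with and without nucleotides at each time, or of A771726 at 48 h and 24 h.

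At 24 h the effect of A771726 differed with nucleotides for 9 genes by limma, and for 308 with the other 23 libraries and 564 with only the groups compared. The fitted difference was -2.98 for PVRL4, -2.84 for BTG2, -2.60 for TXNIP, -2.53 for FDXR and -2.47 for LINC01021 on the log2 scale. ANKRD28 gave 4.36, a value that rests on a group listed at 0 and is no fold. Of 100 splits of the same libraries, 5 gave at least 9 genes with the real split included, the highest other giving 10. The other 4 keep the 3 A771726 libraries together and so carry their effect. The share of 5 in 100 is at the bound of 0.05 set beforehand, so that test did not exclude chance. Among the 96 splits that are real or part the A771726 libraries, only the real 1 gave as many, the highest other giving 1. That set was chosen after the result and leaves out the other 4. It tells only that the A771726 libraries stand apart, not that nucleotides change the effect.

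At 48 h the effect differed with nucleotides for 3746 genes. That count was 500 with median-of-ratios scaling, 937 with quantile normalization, 240 with TPM and 8 with only the groups compared. Fitted values were 4.77 for HIST2H2BA, 4.36 for HIST1H2AJ, 4.30 for UBE2S, 4.29 for HIST1H2BM and 4.62 for the readthrough name SLMO2-ATP5E, which overlaps other genes and is uncertain. These became 3.93, 4.12, 3.68, 2.85 and 4.40 with the other 23 libraries. Values of -4.16 for ANKRD20A12P and -3.75 for LYZ became -2.76 and -2.22 in that fit. EEF1A1 (-10.65), PLCG2 (-8.64) and ANKRD28 (-4.70) are listed at 0 in all 3 libraries with A771726 and nucleotides at 48 h, so these values are no folds. Of 100 splits 3 gave as many genes, a share under the bound of 0.05, the highest other giving 4122. The other 2 keep the A771726 libraries together, and among the 97 that are real or part them only the real 1 gave as many, the highest other giving 2. These splits mix all groups of the time. They tell that the A771726 libraries stand apart at 48 h, and do not decide whether nucleotides change the effect.

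The effect of A771726 differed between 48 h and 24 h for 3700 genes, but for 8 with median-of-ratios scaling, 576 with quantile normalization, 1853 with TPM and 3 with only the groups compared. The higher were SCHIP1 (2.32), LPAR6 (1.51), OR51B5 (1.48), the readthrough name RPS10-NUDT3 (2.92) and the antisense gene VIM-AS1 (2.06), the last pair uncertain because they overlap other genes. The lower were GADD45GIP1 (-3.75), UBE2C (-3.57), CCDC124 (-3.56) and S100A11 (-3.55), which became -2.51, -2.17, -2.70 and -2.22 without replicate 2 of A771726 at 48 h. The short RNA SNAR-D (-4.11) is listed at 0 in whole groups, A771726 at 48 h among them, so its value is no fold. The real split was the only 1 of 100 with as many genes, a share under 0.05, the highest other giving 3667. Even a split that parts the A771726 libraries at 48 h gave 3134. The splits also ignore that same-numbered DMSO libraries deviated together at both times. Counts this close to 3700 mean that the splits do not decide whether the effect differs between the times.

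The p53 targets were higher in A771726 than in DMSO at 24 h, with a list median of 1.36. Removing the trend of each library on GC content and transcript length (96.9% of members had a value) left a median of 1.34, which argues against such a bias as the cause. Without replicate 1 of A771726 at 24 h the median was 1.42, which argues against a single library. With nucleotides in both arms the median was -0.0659, as a shortage of nucleotides under A771726 requires, so p53 activation by that shortage is a candidate explanation.

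The replication-dependent histones were lower in A771726 than in DMSO at 24 h, with a median of -1.60 (camera, adjusted p = 0.00778 with an estimated correlation, and 0.0916 with the other 23 libraries). After the GC and length correction (100% of members) the median was -1.31, which argues against such a bias as the whole cause. Of other protein-coding genes, 146 matched on length and GC content had a median of -0.0724 but were longer (median length 1256 against 642). The 31 no longer than the median histone had a median of -0.0835 (quartiles -0.34 and 0.12). Length is that of the longest annotated transcript of a gene, so genes with a shorter main transcript can be missing from these sets. Ribosomal protein genes had a median of -0.76. These values show no matching fall in the genes of these sets, and do not decide whether short transcripts were lost in general. The S phase list was lower too (-0.36, camera, adjusted p = 0.0208 with an estimated correlation), so fewer cells in S phase, whose share was not measured, may contribute. That list call ended with the other 23 libraries (adjusted p = 0.170). Its median turned positive under TPM scaling (0.12), which also raised the median of all genes, to above that value.

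More genes were lower than higher in A771726 than in DMSO at 48 h. The median of all tested genes was -1.03 in replicate 1, -1.47 in replicate 2 and -0.24 in replicate 3, so the libraries that stand apart may set most of the group value of -0.87. Library scaling stays open, since median-of-ratios scaling lowered the share of lower genes from 92.6% to 65.9%, above the bound of 60% set beforehand. A771726 treatment stays open too, since the median of replicate 3 was below 0 but closer to 0 than the bound, at -0.24. With 1 of 3 libraries like the rest of the series, the treatment and the state of the libraries cannot be told apart for these genes.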

How the results depend on the processing

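The tests with the other 23 libraries (also with the block or the GC and length correction), with the other 22 or 20, with missing zeros, and with the block of the DMSO libraries over both times were chosen after seeing the data. A count test on whole reads was planned and not run, because FPKM hold no counts. In what follows, the inhibitor effect is A771726 against DMSO, the rescue is A771726 with nucleotides against A771726, the nucleotide contrast is the difference of inhibitor effects with and without nucleotides, and the time contrast is that between 48 h and 24 h. The retained slope is that of the response with nucleotides on the response without. It covers the genes that each setting calls for the inhibitor effect at that time, so the gene set changes with the setting. Outside leave-one-out, named genes kept direction and side of the threshold in 1835 cases, lost the threshold in 178, gained it in 20 and reversed in 16. Counts and slopes held in 122 cases and moved in 103, and list calls held in 593, were lost in 100 and had a reversed median in 26. With an estimated correlation 12 of 48 camera calls held. Unless stated, the cause was not tested. Depth is unknown, so its limits could not be given.

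A pseudocount of 0.1 moved the retained slope at 24 h to 0.389 and the NF-kB list in the 48 h rescue to 0.12. No filter on low values gave 473 genes for the inhibitor effect and 384 for the rescue at 24 h, and 5 for A771726 with nucleotides against DMSO at 24 h. It gave 50 for the nucleotide contrast at 24 h, 2 for DMSO over time and a slope of 0.229 at 24 h. A mean of at least 5 FPKM, which tests fewer genes, gave 65 for the inhibitor effect, 33 for the rescue and 4 for the nucleotide contrast at 24 h. It gave 2300 for the time contrast and a slope of 0.376 at 24 h, with NF-kB medians of -0.49 for the inhibitor effect and 0.42 for the rescue at 48 h.

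Median-of-ratios scaling gave 4210 genes for the inhibitor effect, 4199 for the rescue and 500 for the nucleotide contrast at 48 h, and 8 for the time contrast. CDK9 in the 24 h rescue stood at 0.0083 and the interferon median of the 48 h inhibitor effect at 0.087. Quantile normalization gave 267 and 228 genes for the 24 h inhibitor effect and rescue, 4361 and 4368 for those at 48 h, 34 and 937 for the nucleotide contrast at 24 and 48 h, and 576 for the time contrast. The 24 h slope was 0.212. Ribosomal protein medians were 0.0093 for the inhibitor effect and -0.022 for the rescue at 24 h, and interferon medians 0.59 and -0.43 at 48 h. TPM gave 3815 for the inhibitor effect and 240 for the nucleotide contrast at 48 h, 1853 for the time contrast and a slope of -0.011 at 48 h. Its medians for the 24 h inhibitor effect were 0.24 for pyrimidine, 0.23 for purine, 0.12 for S phase and 0.28 for G2/M genes. All of these lay below the median of all genes under that scaling. The G2/M median was -0.13 in the 24 h rescue, and the interferon median was 0.064 for the 48 h inhibitor effect.

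The labels do not say whether a replicate number marks a shared batch. Deviations correlated over 0.1 in 7 of 18 same-numbered pairs at 24 h (lowest -0.28, median 0.08) and 2 of 18 at 48 h (lowest -0.11, median 0.04), and 13 of 24 libraries correlated best with their own number. The correlation of a deviation with GC content was negative for replicate 2 (-0.41 to -0.015) and positive for replicate 3 (0.12 to 0.43) in all 8 groups, so the numbers may mark a shared technical step. All 3 pairs were over 0.1 for DMSO over time but for no other comparison of 2 groups. With the number as a block of the DMSO libraries over both times, limma called 0 genes there (135 unadjusted), the S phase and histone lists gave adjusted p = 0.0482 and 0.0654 with an estimated correlation, and no list call with an estimated correlation changed. With the replicate block within each time 67 genes were higher and 51 lower for the inhibitor effect at 24 h, 549 and 6378 at 48 h, 22 and 53 for the rescue at 24 h, and 6346 and 546 at 48 h. The nucleotide contrast had 3859 higher and 110 lower at 48 h, the time contrast 66 and 3925, and DMSO over time 3 genes, where limma without the block called none (145 unadjusted). Of the counts, that of DMSO alone moved over 1.5 times with the block. With the other 23 libraries and the block, the counts were 1876 and 1394 at 24 h for the inhibitor effect and rescue, 3 and 5 for A771726 with nucleotides against DMSO at 24 and 48 h, 436 and 5674 for the nucleotide contrast, 5833 for the time contrast and 35 for DMSO. Slopes were 0.134 and 0.018, DHODH stood at -0.87 for the inhibitor effect and 0.90 for the rescue at 48 h, and interferon medians at 0.13 and -0.042. Adding the GC and length correction to that block gave 2032 and 1601, 3 and 6, 581 and 5695, and 69 for DMSO, with a 24 h slope of 0.129. DHODH then stood at -0.67 and 0.70, ODF2L in the 48 h rescue at 0.12, and interferon medians at 0.13 and -0.14.

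Only the groups compared, with a spread estimated from fewer libraries, gave 1030 genes for the inhibitor effect and 405 for the rescue at 24 h, but 9 and 8 at 48 h. At 24 h this leaves out the A771726 libraries at 48 h and their spread. At 48 h that spread is no longer shared with all the tighter groups, so the 48 h p-values of the main fit may be too small. A771726 with nucleotides against DMSO gave 2 at 24 h and 5 at 48 h, and nucleotides alone 4 and 4. The nucleotide contrast gave 564 at 24 h and 8 at 48 h, the time contrast 3, DMSO over time 6, and the 24 h slope was 0.154. Limma-trend with robust estimation gave 14 for the nucleotide contrast at 24 h and moved no other count or slope.

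The other 23 libraries gave 1405 genes for the inhibitor effect, 999 for the rescue and 308 for the nucleotide contrast at 24 h, 2 for A771726 with nucleotides against DMSO at 24 h, 3 for DMSO over time and a slope of 0.135. DHODH reversed to -0.83 and 0.87, and interferon medians to 0.17 and -0.024, in the 48 h inhibitor effect and rescue. Without replicate 2 of A771726 at 48 h the median standard error went from 0.377 to 0.204 for the 24 h comparisons, hence the higher counts. The other 22 libraries gave 2888 and 2171 at 24 h and 3381 and 3409 at 48 h for the inhibitor effect and rescue, with the lone A771726 library at 48 h assumed to vary like the other groups. A771726 with nucleotides against DMSO gave 3 and 7, the nucleotide contrast 916 and 1980, the time contrast 868, DMSO 246, and slopes 0.142 and 0.026. DHODH stood at -0.49 and 0.52, and interferon medians at 0.19 and -0.22. The other 20 libraries gave 1142 and 749 at 24 h, 2 for A771726 with nucleotides against DMSO, 285 and 5749 for the nucleotide contrast, 51 for DMSO and slopes of 0.132 and -0.0087. There CDK9 in the 24 h rescue was 0.0904, DHODH -0.83 and 0.87, and interferon 0.17 and -0.024.

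With zeros of expressed genes set to missing, the 24 h inhibitor effect had 200 genes, the rescue 147 and the nucleotide contrast 25, and the slope was 0.0876. Limma then called 0 genes for A771726 with nucleotides against DMSO (34 unadjusted) and 0 for nucleotides alone (19 unadjusted) at 24 h, and 1 for A771726 with nucleotides at 48 h, since PLCG2, EEF1A1 and ANKRD28 hold such zeros. The other 23 libraries with the GC and length correction gave 2118 and 1668 at 24 h, 3 and 7 for A771726 with nucleotides against DMSO, 617 and 5808 for the nucleotide contrast, 5787 for the time contrast, 118 for DMSO and a slope of 0.131. DHODH stood at -0.67 and 0.70, ODF2L at 0.11 in the 48 h rescue, and interferon at 0.15 and -0.16.

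In leave-one-out fits, named genes held in 813 cases, lost the threshold in 118 and reversed in 5, and counts and slopes held in 82 and moved in 32. Each fit was recorded only for comparisons whose groups hold the left-out library, and for the slope of its time. The 24 h ranges below therefore do not cover the fit without replicate 2 of A771726 at 48 h. At 24 h that fit gave 1405 genes for the inhibitor effect, 999 for the rescue, 308 for the nucleotide contrast and a slope of 0.135. The 24 h inhibitor effect ranged from 53 genes without DMSO replicate 1 to 83, and fell to 57, 58 and 62 without A771726 replicate 1 and DMSO replicates 2 and 3. The 24 h rescue ranged from 36 to 51, the low ends being 36 and 38 without replicates 1 and 3 with both additions, and 40 and 46 without A771726 replicates 1 and 3. The nucleotide contrast at 24 h ranged from 5 to 7, with 5 without any library of DMSO or nucleotides at 24 h, A771726 replicate 2 or replicate 1 with both additions. At 48 h it ranged from 2217 without DMSO replicate 1 to 7731 without A771726 replicate 3, with 2264, 2364 and 2332 without DMSO replicate 3, nucleotides replicate 2 and replicate 3 with both additions. The time contrast ranged from 1176 without DMSO 24 h replicate 2 to 7731 without A771726 48 h replicate 3. It was 2291, 2076, 1983 and 1492 without DMSO 24 h replicate 1, A771726 24 h replicate 3, and DMSO 48 h replicates 1 and 3. DMSO over time ranged from 0 by limma to 4 without DMSO 48 h replicate 3 (80 unadjusted). The 24 h slope ranged from 0.244 to 0.373, with 0.369, 0.360 and 0.373 without DMSO replicates 1 and 2 and A771726 replicate 1, and the 48 h slope from -0.0064 to 0.0216 (the latter without nucleotides replicate 2). In the 24 h rescue HEXIM1 ranged from -0.24 to 0.0816 and CDK9 from -0.18 to 0.12, both highest without A771726 replicate 1, and CDK9 was 0.0345 without replicate 1 with both additions. DHODH at 48 h ranged from -0.83 to 0.94 for the inhibitor effect and from -0.91 to 0.87 for the rescue, its sign turning without A771726 replicate 2.

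Limits of these data are 3 libraries per group, separate cultures that the labels do not state, FPKM without counts or depth, and expressed genes listed at 0 in whole groups. At 48 h, A771726 is represented by libraries that stand apart in 2 of 3 cases. The identity and dose of the nucleotides are not given in the sources used here, and proteins, cell numbers and cell cycle shares were not analysed here.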

Other observations

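The test of shared genes between the times was chosen after the result was seen, as were the values with the other 23 libraries.

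With A771726 and nucleotides at 48 h, aryl hydrocarbon receptor targets lay above DMSO. Over 5 measured members the median log2 fold change was 0.38 (camera, adjusted p = 2.39e-07 at the preset correlation and 5.42e-04 with an estimated correlation). The members were CYP1A1 (0.50), TIPARP (0.49), NQO1 (0.38), AHRR (0.32) and AHR (0.00), and limma called none (3 adjusted over the list alone with the other 23 libraries, none with all 24). TIPARP averaged 10.7 ± 1.87 FPKM in DMSO and 15.3 ± 1.00 FPKM with both additions (SD, n = 3). At 24 h the median was 0.25 (adjusted p = 0.274 with an estimated correlation). In DMSO, with the replicate number as a block, this list was lower at 48 h than at 24 h. There camera gave adjusted p = 0.0128 at the preset correlation and 0.0716 with an estimated correlation. The DMSO libraries at 48 h enter both comparisons.

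At 48 h of A771726 against DMSO, 6404 of all 12042 genes were lower by limma, with a median of all genes of -0.87. There 18 of 27 pyrimidine and 15 of 18 purine genes were lower, with medians of -1.37 and -1.56 (adjusted p = 0.530 each with an estimated correlation). TK1, the cytosolic thymidine kinase, fell by 2.50 on the log2 scale. In the list of P-TEFb and its partners 18 of 28 were lower and 1 higher (median -1.13, adjusted p = 0.574 with an estimated correlation), and NELFE fell by 2.55 on the log2 scale. The neural crest list had 16 of 25 lower (median -1.20, adjusted p = 0.530 with an estimated correlation), and the transcription factor FOXD3 fell by 2.25. In the cholesterol list 14 of 22 were lower, while STARD4, a cholesterol carrier, rose from 5.83 ± 0.803 to 26.2 ± 10.3 FPKM (1.93 ± 0.22, limma, adjusted p = 1.76e-05). The median of that list was -1.13 (adjusted p = 0.908 with an estimated correlation).

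A hypothesis of slower transcription elongation would lower long genes more than short ones. Across genes, which are not independent replicates, the Spearman correlation of the 24 h log2 fold change with gene span was 0.14, and 0.04 after the GC and length correction. Both are above 0, so long genes were not lowered more than short ones. FPKM measure RNA levels and not elongation, and short genes such as the histones fell, which raises this correlation. These values therefore do not decide whether elongation was slower.

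A hypothesis is that the same genes may respond to A771726 at both times. Of the genes higher at 24 h, 31 were higher at 48 h, against 2.50 for independent lists (a ratio of 12.4). Of those lower, 53 of 55 were lower at 48 h, against 29.2 (a ratio of 1.81), close to the ceiling set by the 6404 lower genes at 48 h. With the other 23 libraries the shared genes were 328 against 51.0 and 476 against 310.7. The expected numbers take the lists as independent, while same-numbered DMSO libraries of both times deviated together, so part of the excess may come from the controls.

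Replicate 1 of A771726 at 24 h, replicate 2 of A771726 with nucleotides at 24 h and replicate 3 of nucleotides at 48 h deviated from their groups in the same genes, with a smallest pairwise correlation of 0.29 across genes (0.36 after the GC and length correction) and a smallest correlation with GC content of -0.30. Genes near 0 in most libraries were above 0 in at least 9.58% of cases in each of the 3, against a median of 8.06% and a highest value of 14.2% in the others.

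Splits of 3 against 3 libraries number 10, too few for a share under 0.05. A771726 against DMSO gave 114 genes at 24 h (highest other split 0) and 6915 at 48 h (4847). Nucleotides added to A771726 gave 72 genes at 24 h (highest other 0) and 6903 at 48 h (3684). A771726 with nucleotides against DMSO gave 1 gene at 24 h (0) and 3 at 48 h (1), and nucleotides alone 1 at 24 h (0) and by limma 0 at 48 h (37 unadjusted, highest other 1). DMSO at 48 h against 24 h gave 0 by limma (145 unadjusted, highest other 1), as did the other splits that part all 3 same-numbered pairs, while each split with 1 gene kept a pair together.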
